A study of Homo sapiens with 8 samples.

How the data were processed

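RNA from ES2 cells, a human ovarian cancer line, was profiled by RNA sequencing in 8 libraries, 2 in each of 4 groups. Control cells and KDM1A knockout cells had each received vehicle or 5 µM LY500307, an agonist of oestrogen receptor beta, for 48 h, per the labels' protocols. The protocols name total RNA isolated on spin columns, Illumina TruSeq libraries and single-end reads. They name both a stranded mRNA kit and a total RNA guide, and the strand setting of the counting is not given in the sources used here, so a gene and an overlapping antisense gene cannot be told apart. Duplicates are described as sequencing runs and nothing says that they came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The position of the KDM1A edit, and whether the knockout cells are a clone or a pool, are not given in the sources used here.

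The deposited files hold whole-number read counts per gene symbol, made by the authors with bcl2fastq, TopHat2 2.0.8b and HTSeq on hg19, per the submitters' processing notes. Per the labels' series text, reads of the duplicates were combined before alignment, yet each library has its own file and the values of paired files differ. Within each group the duplicates differed by more than counting noise (chi-square per degree of freedom of 3.21 to 4.64). All 8 were kept as separate samples, although such a difference does not show that they came from separate cultures. Summary entries of the counter were removed before library sizes were computed. Reads aligned outside annotated genes made up 10.7% to 12.8% of uniquely aligned reads and ambiguous reads 0.811% to 0.861%. There were 46.6 to 52.8 alignments that were not unique per 100 uniquely aligned reads, and the entries for low quality and unaligned reads stood at 0. The number of sample columns left unused was 0.

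Library totals over genes lay between 24348937 and 30131097 counts, and 15233 to 15809 genes had a count in a library. A floor of 3 counts over a group was used for folds against a group without counts, and counting intervals are at the 95% level. These floors and intervals cover counting error only, since no molecular identifiers are named in the sources used here. Intervals of medians over genes came from 10000 bootstrap draws of genes and do not measure the spread between libraries. Counts were analysed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Of 23228 genes listed, 5520 had no count, and filterByExpr kept 13498 for testing. Library sizes were scaled by TMM. One quasi-likelihood model with a mean for each of the 4 groups was fitted to all 8 libraries, which left 4 residual degrees of freedom per gene and a prior of 30.1. The biological coefficient of variation was 3.95%. Each of 6 comparisons was tested with glmQLFTest (two-sided) and Benjamini-Hochberg adjustment over all genes tested at 0.05. The 6 comparisons were knockout against control under each treatment, LY500307 against vehicle in each cell population, both factors together, and the interaction. Values per group are CPM, counts relative to the TMM-scaled library size, as mean ± SD of 2 libraries.

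The comparisons, the tests, 42 gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. Lists were tested with camera at a preset correlation of 0.01, adjusted by Benjamini-Hochberg over the lists of a comparison. Camera with an estimated correlation, camera on ranks and fry were run beside it. The lists held 1167 entries, of which 1148 were found. Of the 42 lists, 40 were tested and 2 had fewer than 5 measured genes. They include haematopoietic, endothelial, and mesothelial and fibroblast markers as signs of other cell types. Named genes are KDM1A, ESR1 and ESR2, and per comparison the 10 largest rises and 10 largest falls among genes past the threshold with a mean of at least 5 CPM in a compared group and no overlap between the libraries of the groups compared. The interaction had no such overlap condition, and 5 and 5 were taken for it, for knockout against control under LY500307 and for both factors together. Symbols of uncharacterised, small or antisense RNAs were left out. From each list described, up to 4 members were taken by smallest p among those past the threshold, or by highest mean CPM where fewer than 2 passed. GPER was added after its values were seen. Results of some genes that the rule names are not reported here.

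Gene positions came from GENCODE release 44 lifted to GRCh37, matched by symbol for 18908 genes and by older symbol for 2138, with 2182 unmatched. Its gene bounds can differ from those of the annotation used for counting. Arm medians used 12772 tested genes on the 41 arms with at least 20 of them. The procedure was tested on counts simulated from the means and dispersions of the fit. In these, 200 genes with a mean of at least 1 CPM were changed in 1 group. The rates below hold for that setting and need not carry over to lower genes or to comparisons with many more changed genes. For LY500307 in control cells (13332 genes) it recovered 74%, 84%, 98% and 100% of genes changed 1.25-, 1.5-, 2- and 4-fold, with 6 false calls among 184. For the interaction (13338 genes) it recovered 18%, 72%, 88% and 100%, with 1 false call among 140.

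Alternatives were DESeq2 size factors and library totals in place of TMM, DESeq2 1.42.0 as the test, no filter, a stricter filter (5 CPM in at least 2 libraries), replicate number as a block, a minimum log2 change of 1, the 4 compared libraries alone, and leaving out each library in turn. Centring of knockout effects by chromosome arm, removal of genes at least 10-fold higher in knockout vehicle libraries and a split of the vehicle control libraries between comparisons were added after seeing the data. Correlations between fold changes are across genes, which are not independent replicates, and carry no p-value. For the pair of comparisons that share the vehicle-treated control libraries, 100 simulations of unchanged groups gave the value expected without any effect. Genes without a count in those libraries were left out of the simulated values. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.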

Results

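Gene expression was measured by RNA sequencing in ES2 ovarian cancer cells with or without knockout of KDM1A, a histone demethylase that removes methyl groups from lysine 4 of histone H3. Cells of both kinds received vehicle or LY500307, an agonist of oestrogen receptor beta, at 5 µM for 48 h. The study asked how loss of KDM1A bears on the response to oestrogen receptor beta in ovarian cancer. Each of the 4 groups held 2 libraries. Total gene counts were 24422873 and 24348937 for vehicle-treated control cells and 24849008 and 30131097 for vehicle-treated knockout cells. With LY500307 they were 28319768 and 27693424 for control cells and 25906633 and 27538721 for knockout cells. The most abundant transcript in each library was that of the collagenase MMP1, with 1.79% to 2.47% of gene counts. Values are means ± SD with n = 2 per group, and single values beside a gene are log2 fold changes, some with their standard error (SE). Genes named among the largest changes of a pair of groups had both libraries of 1 group above both of the other.

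The KDM1A transcript (hg19 chromosome 1, 23345936 to 23410182) was lower in every library labelled knockout. It stood at 220 and 219 CPM in vehicle-treated control cells and at 75.6 and 77.8 CPM in vehicle-treated knockout cells, or 34.9% of control. Under LY500307 it stood at 238 and 241 CPM in control and at 72.0 and 71.6 CPM in knockout cells, or 29.9% of control. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the log2 fold changes were -1.52 (SE 0.05, adjusted p = 4.21e-24) and -1.74 (SE 0.05, adjusted p = 5.92e-26), lower in 4 of 4 knockout libraries. With LY500307 KDM1A changed by 0.13 in control cells (edgeR adjusted p = 0.0440) and by -0.10 in knockout cells (adjusted p = 0.194). The former call was lost without any 1 of its libraries, with edgeR adjusted p of 0.147 and 0.170 without control vehicle replicates 1 and 2 and of 0.1253 and 0.2001 without control LY500307 replicates 1 and 2. Counts cover the whole gene and do not show the edited part of the transcript. The receptor genes had few counts. ESR2, which encodes oestrogen receptor beta, had 8, 10, 11 and 12 counts over the 2 libraries of vehicle control, vehicle knockout, LY500307 control and LY500307 knockout cells, too few to be tested. ESR1, which encodes oestrogen receptor alpha, had 23, 16, 22 and 15 counts, and no difference was detectable at this depth. GPER, the G protein-coupled oestrogen receptor gene, stood at 0.768 ± 0.121 CPM in vehicle-treated control and 3.30 ± 0.0297 CPM in vehicle-treated knockout cells, a log2 fold change of 2.10 (SE 0.28). It was chosen after its values were seen.

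**Figure D1:**
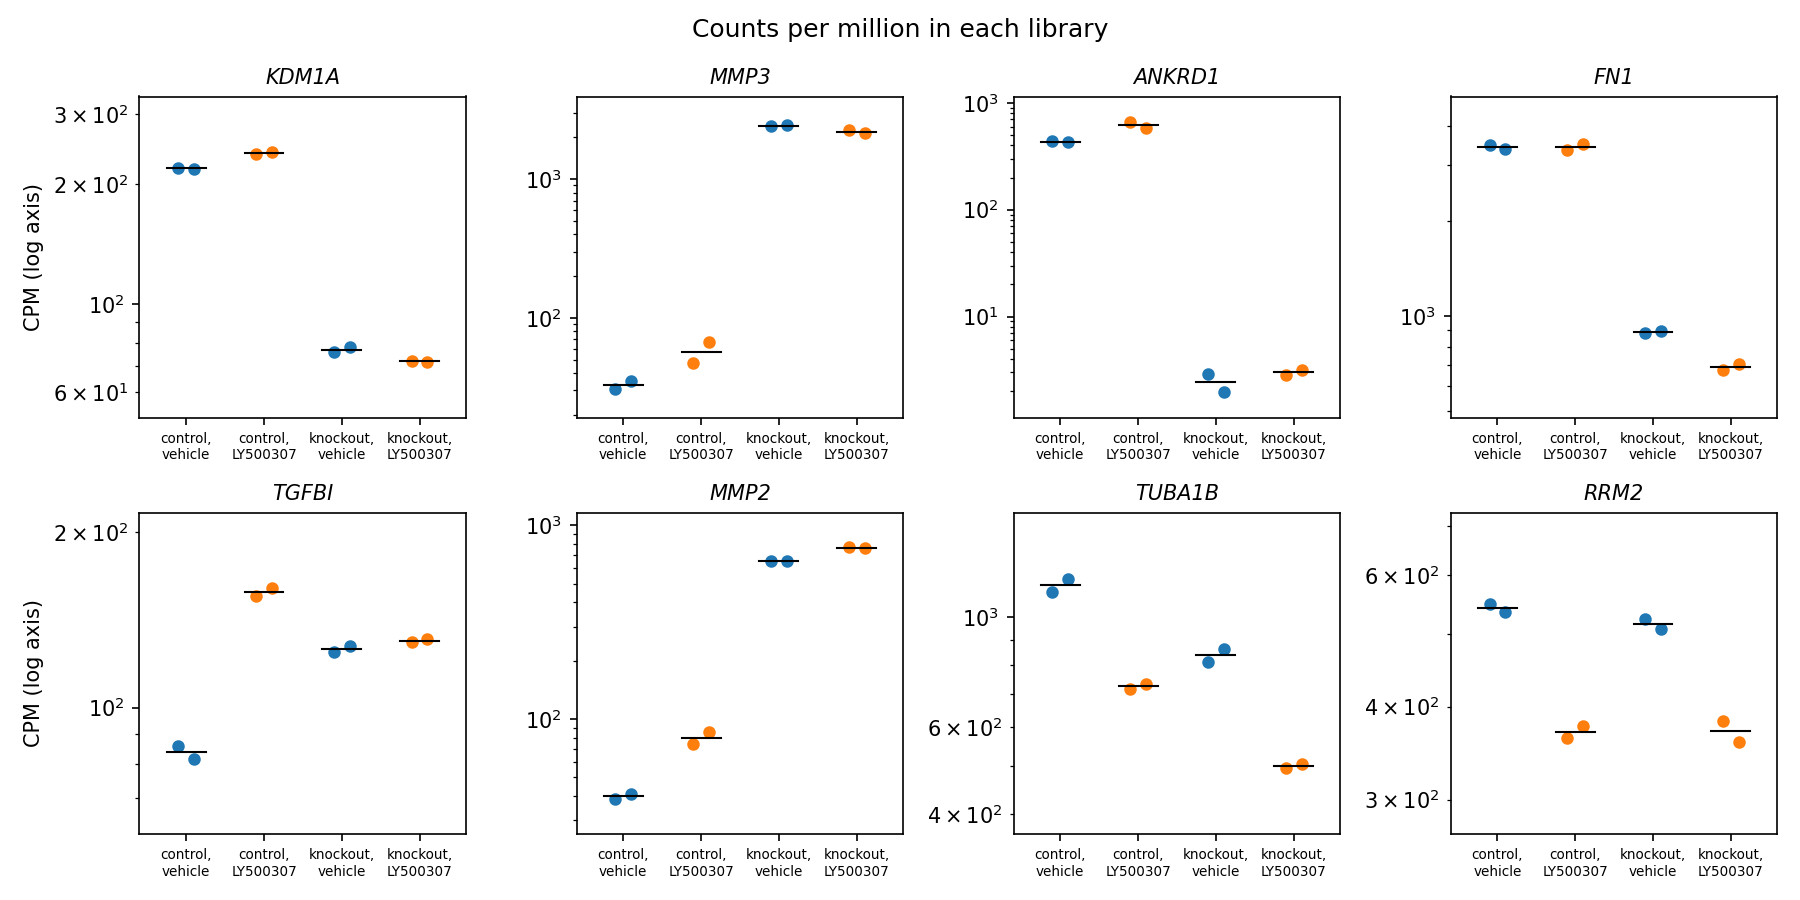
CPM on a log axis for KDM1A, MMP3, ANKRD1, FN1, TGFBI, MMP2, TUBA1B and RRM2 in control and knockout cells with vehicle (blue) or LY500307 (orange); points are libraries and bars are group means of 2 libraries. KDM1A lay at 219 to 241 CPM in the control libraries and at 71.6 to 77.8 CPM in the knockout libraries, and TUBA1B and RRM2 were lower with LY500307 in both cell populations.

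The first comparison set knockout against control cells without agonist. No separate knockout clones are described, so effects of KDM1A loss cannot be told apart from other differences between the cell populations. That limit holds for each comparison of knockout with control cells and for the interaction. MMP3, the stromelysin protease (chromosome 11, 102706532 to 102714340), rose from 33.0 ± 2.91 to 2429 ± 9.45 CPM, a log2 fold change of 6.20 (SE 0.084; edgeR quasi-likelihood test with Benjamini-Hochberg adjusted p = 2.21e-35, higher in 2 of 2 libraries). MGAM, an intestinal glucosidase, rose from 0.256 to 121 CPM, and IL13RA2, a decoy receptor for interleukin 13, from 1.79 ± 0.122 to 349 ± 4.37 CPM. The myeloid lectin CLEC5A (chromosome 7, 141627157 to 141646807) had no count in control cells and 59.6 ± 2.40 CPM in knockout cells, at least 929-fold higher. NCAM2, a neural adhesion molecule (chromosome 21, 22370727 to 22915650), fell from 39.0 CPM to no count, at least 710-fold lower.

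BST2, the interferon-inducible membrane protein tetherin, rose with a log2 fold change of 7.09 (SE 0.26), the folate-binding protein gene FOLR3 with 7.12 (SE 0.30), the sarcoglycan SGCZ with 6.34 (SE 0.16) and the butyrophilin-like BTNL8 with 6.14 (SE 0.22). The cadherin CDH19 rose by a ratio of 239 (95% counting interval 65.9 to 1981). Genes without a count in vehicle-treated knockout cells included the calcium channel subunit CACNG8 (at least 258-fold lower), PTPRN2 of secretory granules (at least 220-fold), the ectodysplasin A2 receptor EDA2R (at least 102-fold), the peptide receptor VIPR1 (at least 101-fold) and the cancer-testis antigen MAGEA6 (at least 94.7-fold), which shares sequence with near-identical copies and is uncertain. The protease TMPRSS15 was lower by a ratio of 1150 (393 to 5581) and the adhesion receptor VCAM1 by 958 (265 to 7916).

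Targets of the transcriptional coactivator YAP were lower in knockout cells. Of 21 measured, 2 rose and 16 fell (2 and 17 adjusted over the list alone), with camera adjusted p = 3.12e-09 and adjusted p = 0.150 with an estimated correlation. ANKRD1, a cardiac ankyrin repeat protein and YAP target, fell from 434 ± 3.04 to 2.42 ± 0.637 CPM (log2 fold change -7.51), the insulin-like growth factor carrier IGFBP3 changed by -4.34, CRIM1 by -1.89 and the matricellular protein CTGF by -1.39. WNT pathway genes went the same way, with 3 higher and 12 lower of 19 (4 and 12 adjusted over the list alone; camera adjusted p = 3.52e-05, adjusted p = 0.231 with an estimated correlation). The members with the smallest p-values included DKK3 (-1.96) and, as secreted antagonists of WNT signalling, SFRP1 (-1.91) and DKK1 (-0.91). The ligand WNT5B changed by -2.37. Stemness genes fell in 10 of 16 and rose in 4, the same numbers adjusted over the list alone (camera adjusted p = 0.00129, adjusted p = 0.231 with an estimated correlation, 0.0581 by camera on ranks). Among these were the surface marker THY1 (33.5 ± 3.34 to 0.0775 ± 0.0622 CPM), the drug efflux pump ABCG2 (-2.45) and the receptor LGR5 (-2.45).

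NF-kB targets and inflammatory cytokines rose in knockout cells, 23 of 32 higher and 4 lower (the same adjusted over the list alone), with camera adjusted p = 3.70e-08 and adjusted p = 0.150 with an estimated correlation. Besides MMP3 these included the cytokine IL24 (4.65), the apoptosis inhibitor BIRC3 (1.65) and the ubiquitin-editing enzyme TNFAIP3 (1.19). Autophagy and lysosome genes rose in 21 of 31 and fell in 3, the same adjusted over the list alone (camera adjusted p = 0.00129, adjusted p = 0.231 with an estimated correlation), among them the cargo receptor SQSTM1 (0.76), ATG2A (1.07) and the cholesterol carrier NPC2 (1.33). In the integrated stress response group around ATF4, 20 of 33 rose and 6 fell, the same adjusted over the list alone (camera adjusted p = 0.00142, adjusted p = 0.231 with an estimated correlation). SLC3A2, a subunit of amino acid transporters, rose by 1.19 and the stress sensor SESN2 by 1.07, while CHAC1, a glutathione-degrading enzyme, changed by -3.33. Targets of the oxidative stress factor NRF2 rose in 14 of 25 and fell in 3, the same adjusted over the list alone (camera adjusted p = 0.00491, adjusted p = 0.228 with an estimated correlation). HMOX1, which degrades haem, rose from 9.49 ± 0.99 to 79.9 ± 3.90 CPM.

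Hypoxia and glycolysis genes fell in 21 of 33 and rose in 4, the same adjusted over the list alone (camera adjusted p = 0.000366, adjusted p = 0.231 with an estimated correlation). The lactate exporter SLC16A3 fell from 36.4 ± 1.26 to 0.947 ± 0.0797 CPM, and the glycolytic enzymes PGK1 and HK2 changed by -0.87 and -0.92. Genes of the G1/S transition and DNA replication fell in 26 of 43 and rose in 4 (27 and 4 adjusted over the list alone; camera adjusted p = 0.0039, adjusted p = 0.228 with an estimated correlation), among them TYMS (-1.75), MCM4 (-0.82) and TK1 (-0.73). Mesenchymal genes went both ways, 16 higher and 17 lower of 36 (the same adjusted over the list alone), with camera adjusted p = 0.00258 towards lower values, adjusted p = 0.289 with an estimated correlation and 0.813 by camera on ranks. Their mean was -0.48 and their median -0.0042, which turned to 0.04 with library totals and to 0.0068 with the size factors of DESeq2. The gelatinase MMP2 rose from 39.9 ± 1.83 to 653 ± 0.721 CPM, while fibronectin FN1 fell from 3422 ± 76.2 to 890 ± 10.0 CPM and the collagen gene COL1A1 and the thrombospondin THBS1 changed by -2.47 and -3.23. Oestrogen-responsive genes rose in 4 of 17 and fell in 7 (the same adjusted over the list alone), and the list did not pass (camera adjusted p = 0.751). Nor did the markers of other cell types pass. Haematopoietic markers were higher in 3 of 8 and lower in 2 (3 and 3 adjusted over the list alone; camera adjusted p = 0.701), with a median of -0.20 against a mean of 0.36 and a test towards higher values. Endothelial markers were higher in 3 of 7 and lower in 2 (camera adjusted p = 0.947), with a median of 0.20 against a mean of -0.02 and a test towards lower values. Mesothelial and fibroblast markers were higher in 4 of 9 and lower in 4 (camera adjusted p = 0.103), and for both these lists the counts adjusted over the list alone were the same.

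In all, 8637 of 13498 genes tested differed between knockout and control cells with vehicle, 4146 higher and 4491 lower, of which 803 and 1070 changed at least 2-fold. The balance turned with library totals, to 4580 higher and 4037 lower. Knockout effects also differed between chromosome arms. Median log2 fold changes were -0.92 on 18p, -0.78 on 5p and -0.66 on 16p, against 0.28 on 1p, which carries KDM1A, and 0.33 on 2q. TYMS lies on 18p, ALDOA and ABCC1 lie on 16p, and MCM4 on 8q (-0.36). When the arm medians were removed, an alternative added after seeing the data, 7469 genes passed, 6269 of them among the 8637, and 723 changed sign. All 10 lists described as passing with vehicle passed again. Lower were 16 of 21 YAP targets, 13 of 19 WNT pathway genes, 9 of 15 stemness genes, 22 of 33 hypoxia and glycolysis genes and 26 of 43 G1/S genes. Higher were 22 of 32 NF-kB targets, 24 of 31 autophagy genes, 15 of 31 ATF4 genes and 12 of 25 NRF2 targets, while mesenchymal genes were higher in 15 and lower in 18.

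**Figure D2:**
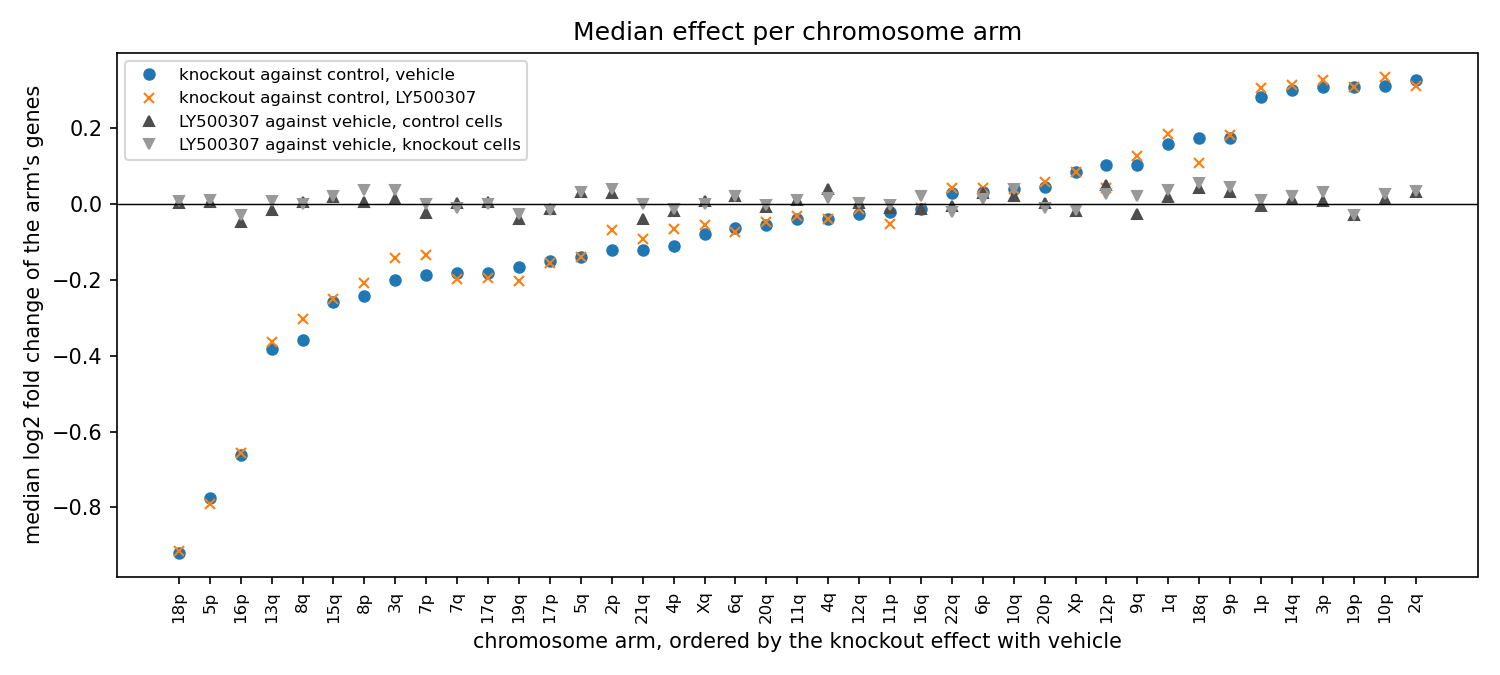
Median log2 fold change of the genes on each of 41 chromosome arms, for knockout against control with vehicle and with LY500307 and for LY500307 against vehicle in each cell population. Knockout medians ran from -0.92 (18p) to 0.33 (2q) with vehicle, while those of LY500307 against vehicle stayed between -0.05 and 0.06.

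The second comparison asked how LY500307 changed control cells. G1/S and DNA replication genes fell in 32 of 43 and microtubule and tubulin genes in 9 of 14, and both lists passed with an estimated correlation (camera adjusted p = 0.00884 and 0.0227). RRM2, a subunit of ribonucleotide reductase (chromosome 2, 10260825 to 10351851), fell from 542 ± 8.97 to 370 ± 9.20 CPM, a log2 fold change of -0.55 (SE 0.043). Alpha-tubulin TUBA1B (chromosome 12, 49521565 to 49525180) fell from 1161 ± 51.1 to 725 ± 11.4 CPM, although tubulin copies share sequence and their split is uncertain. The interleukin gene IL1B rose from 71.5 ± 2.13 to 128 ± 0.93 CPM and HMOX1 from 9.49 ± 0.99 to 21.1 ± 3.03 CPM.

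The largest rises included the phospholipase PLCH2 (1.51, SE 0.23), the lymphocyte adaptor SH2D1B (1.47, SE 0.18), the endoplasmic reticulum shaping protein REEP6 (1.36, SE 0.19), and DISP2 (1.33, SE 0.18). They also included the interleukin 7 receptor IL7R (1.18, SE 0.13), the neuropeptide precursor VGF (1.16, SE 0.19), the sterol reductase TM7SF2 (1.12, SE 0.19), the phosphodiesterase PDE2A (1.12, SE 0.17) and PFKFB4, a regulator of glycolysis (1.08, SE 0.087). The largest falls were smaller. They included the G protein regulator RGS5 (-0.93, SE 0.18), the leptin receptor LEPR (-0.81, SE 0.11), the adhesion receptor GPR98 (-0.80, SE 0.19), the peroxisomal membrane protein PXMP2 (-0.77, SE 0.11) and ARHGAP22, which inactivates small GTPases (-0.74, SE 0.066).

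G1/S and DNA replication genes fell in 32 of 43 and rose in 0 (36 lower adjusted over the list alone), with a median of -0.32, camera adjusted p = 7.22e-25 and adjusted p = 0.00884 with an estimated correlation. CDC25A, a phosphatase that activates cyclin-dependent kinases, changed by -0.54, the transcription factor E2F1 by -0.56 and the methylation maintenance factor UHRF1 by -0.53. Homologous recombination and DNA repair genes fell in 19 of 34 and rose in 2 (20 and 3 adjusted over the list alone; camera adjusted p = 2.60e-06, adjusted p = 0.190 with an estimated correlation), including MSH6 (-0.41), FANCI (-0.44) and RAD54L (-0.52). Genes of G2/M and mitosis did not pass as a list (4 higher and 10 lower of 41, 5 and 12 adjusted over the list alone, camera adjusted p = 0.554), and their median of -0.02 turned to 0.05 when libraries were scaled by their totals. Microtubule and tubulin genes, a list of tubulins with STMN1, MAP4, MAP1B and TTC5, fell in 9 of 14 and rose in 0, the same adjusted over the list alone (camera adjusted p = 6.60e-14, adjusted p = 0.0227 with an estimated correlation), with TUBA1C at -0.60 and TUBB at -0.52. Outside that list, epsilon-tubulin TUBE1 rose by 0.57 (edgeR adjusted p = 5.47e-05) and was chosen after its value was seen. Ribosomal protein genes, whose reads can be shared with pseudogenes, fell in 48 of 57 and rose in 0 (51 lower adjusted over the list alone; camera adjusted p = 8.92e-21, adjusted p = 0.190 with an estimated correlation). RPS23 changed by -0.52 and RPLP0 by -0.32, and 34 of the 57 were lower with library totals. MYC targets and ribosome biogenesis genes fell in 18 of 36 and rose in 0 (21 lower and 2 higher adjusted over the list alone; camera adjusted p = 3.36e-08, adjusted p = 0.172 with an estimated correlation), among them NOP56 (-0.37) and the RNA helicase DDX21 (-0.30). Nuclear genes of oxidative phosphorylation fell in 12 of 42 and rose in 0, the same adjusted over the list alone (camera adjusted p = 0.000409, adjusted p = 0.210 with an estimated correlation). With library totals 9 were lower and 3 higher.

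Interferon-stimulated genes rose in 13 of 40 and fell in 1, the same adjusted over the list alone (camera adjusted p = 5.73e-05, adjusted p = 0.190 with an estimated correlation). IFIT1, which binds viral RNA, rose from 4.37 ± 0.093 to 9.04 ± 0.318 CPM, the GTPase GBP1 by 0.94 and the antiviral factor SAMD9L by 0.82. NF-kB targets and cytokines rose in 13 of 32 and fell in 3, the same adjusted over the list alone (camera adjusted p = 0.000745, adjusted p = 0.190 with an estimated correlation), with MMP3 at 0.79, IL8 at 0.40 and the chemokine CXCL5 at -0.41. MMP3 stood at 47.2 and 66.6 CPM in LY500307-treated control replicates 1 and 2, against 33.0 CPM with vehicle and 2429 CPM in vehicle-treated knockout cells. Neuronal genes rose in 7 of 16 and fell in 1, the same adjusted over the list alone (camera adjusted p = 0.00231, adjusted p = 0.190 with an estimated correlation). The neurofilament NEFL rose by 0.72 and secretogranin SCG2 by 1.38. Mesenchymal genes rose in 10 of 36 and fell in 5 (13 and 5 adjusted over the list alone; camera adjusted p = 0.00579, adjusted p = 0.210 with an estimated correlation, 0.127 on ranks). TGFBI, an extracellular matrix protein induced by TGF-beta, rose from 83.8 ± 2.94 to 158 ± 3.52 CPM, MMP2 by 1.00, and the collagen COL6A3 changed by -0.40. TGF-beta targets rose in 9 of 26 and fell in 5, the same adjusted over the list alone (camera adjusted p = 0.00667, adjusted p = 0.190 with an estimated correlation, 0.131 on ranks). Hypoxia and glycolysis genes rose in 13 of 33 and fell in 8 (14 and 10 adjusted over the list alone; camera adjusted p = 0.0105, adjusted p = 0.346 with an estimated correlation, 0.217 on ranks), with NDRG1 at 0.75, the carbonic anhydrase CA9 at 0.93 and GAPDH at -0.28. In the list of polyadenylated histone and replication-dependent histone genes, 4 of 7 rose and 0 fell (5 higher adjusted over the list alone). The camera adjusted p was 0.000679, and 0.210 with an estimated correlation. Transcripts of replication-dependent histone genes mostly lack a poly(A) tail, and the list does not tell both kinds apart. Copies of histone genes share sequence and are uncertain. Levels were low, with HIST1H2BD rising from 1.02 ± 0.0597 to 3.44 ± 0.0748 CPM.

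Several further lists lost their call under at least 1 alternative. Heat shock and immediate early genes rose in 13 of 26 and fell in 5 (14 and 6 adjusted over the list alone; camera adjusted p = 0.0245, adjusted p = 0.190 with an estimated correlation), with DUSP1 at 0.36 and JUN at -0.35. The camera adjusted p of that list was 0.0715 without control vehicle replicate 2 and 0.0525 without control LY500307 replicate 2. Autophagy and lysosome genes rose in 8 of 31 and fell in 0 (9 higher adjusted over the list alone; camera adjusted p = 0.0199, adjusted p = 0.308 with an estimated correlation), with GABARAPL1 at 0.75. Without control LY500307 replicate 2 its camera adjusted p was 0.134, and on ranks it was 0.182. Cholesterol synthesis genes rose in 7 of 25 and fell in 1, the same adjusted over the list alone (camera adjusted p = 0.0332, adjusted p = 0.346 with an estimated correlation), TM7SF2 and SQLE (0.24) among them. The camera adjusted p was 0.0715 without control vehicle replicate 2 and 0.122 without control LY500307 replicate 1. Haematopoietic markers rose in 4 of 8 and fell in 0 (6 higher adjusted over the list alone; camera adjusted p = 0.0241, adjusted p = 0.196 with an estimated correlation, 0.0615 with library totals). Among the members, CD68 (0.18) and LCP1 (0.53) lost their call without any 1 of the 4 libraries compared, with edgeR adjusted p of 0.0675 to 0.174 and of 0.0677 to 0.233, and by DESeq2 (adjusted p = 0.0583 and 0.0912). The receptor chain FCER1G (1.57) lost it without control vehicle replicates 1 and 2 and control LY500307 replicate 2 (edgeR adjusted p of 0.103, 0.0720 and 0.0941). ITGAX (1.70) lost it without control vehicle replicates 1 and 2 and control LY500307 replicate 1 (edgeR adjusted p of 0.0817, 0.183 and 0.355), the last with a log2 fold change of 1.10. Endothelial markers (1 higher and 2 lower of 7, camera adjusted p = 0.906) and mesothelial and fibroblast markers (2 and 1 of 9, camera adjusted p = 0.679) did not pass, with the same numbers adjusted over the list alone. The median of the latter was -0.15 and the mean -0.40, against a test towards higher values. Oestrogen-responsive genes did not pass either, with 4 higher and 3 lower of 17 and the same numbers adjusted over the list alone (camera adjusted p = 0.679).

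With LY500307, 3550 genes changed in control cells, 1665 higher and 1885 lower, 186 and 45 of them by at least 2-fold. Scaling by library totals gave 2831 higher and 1011 lower. The count fell to 2326 and 2160 without control vehicle replicates 1 and 2, and to 2203 and 2188 without control LY500307 replicates 1 and 2.

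**Figure D3:**
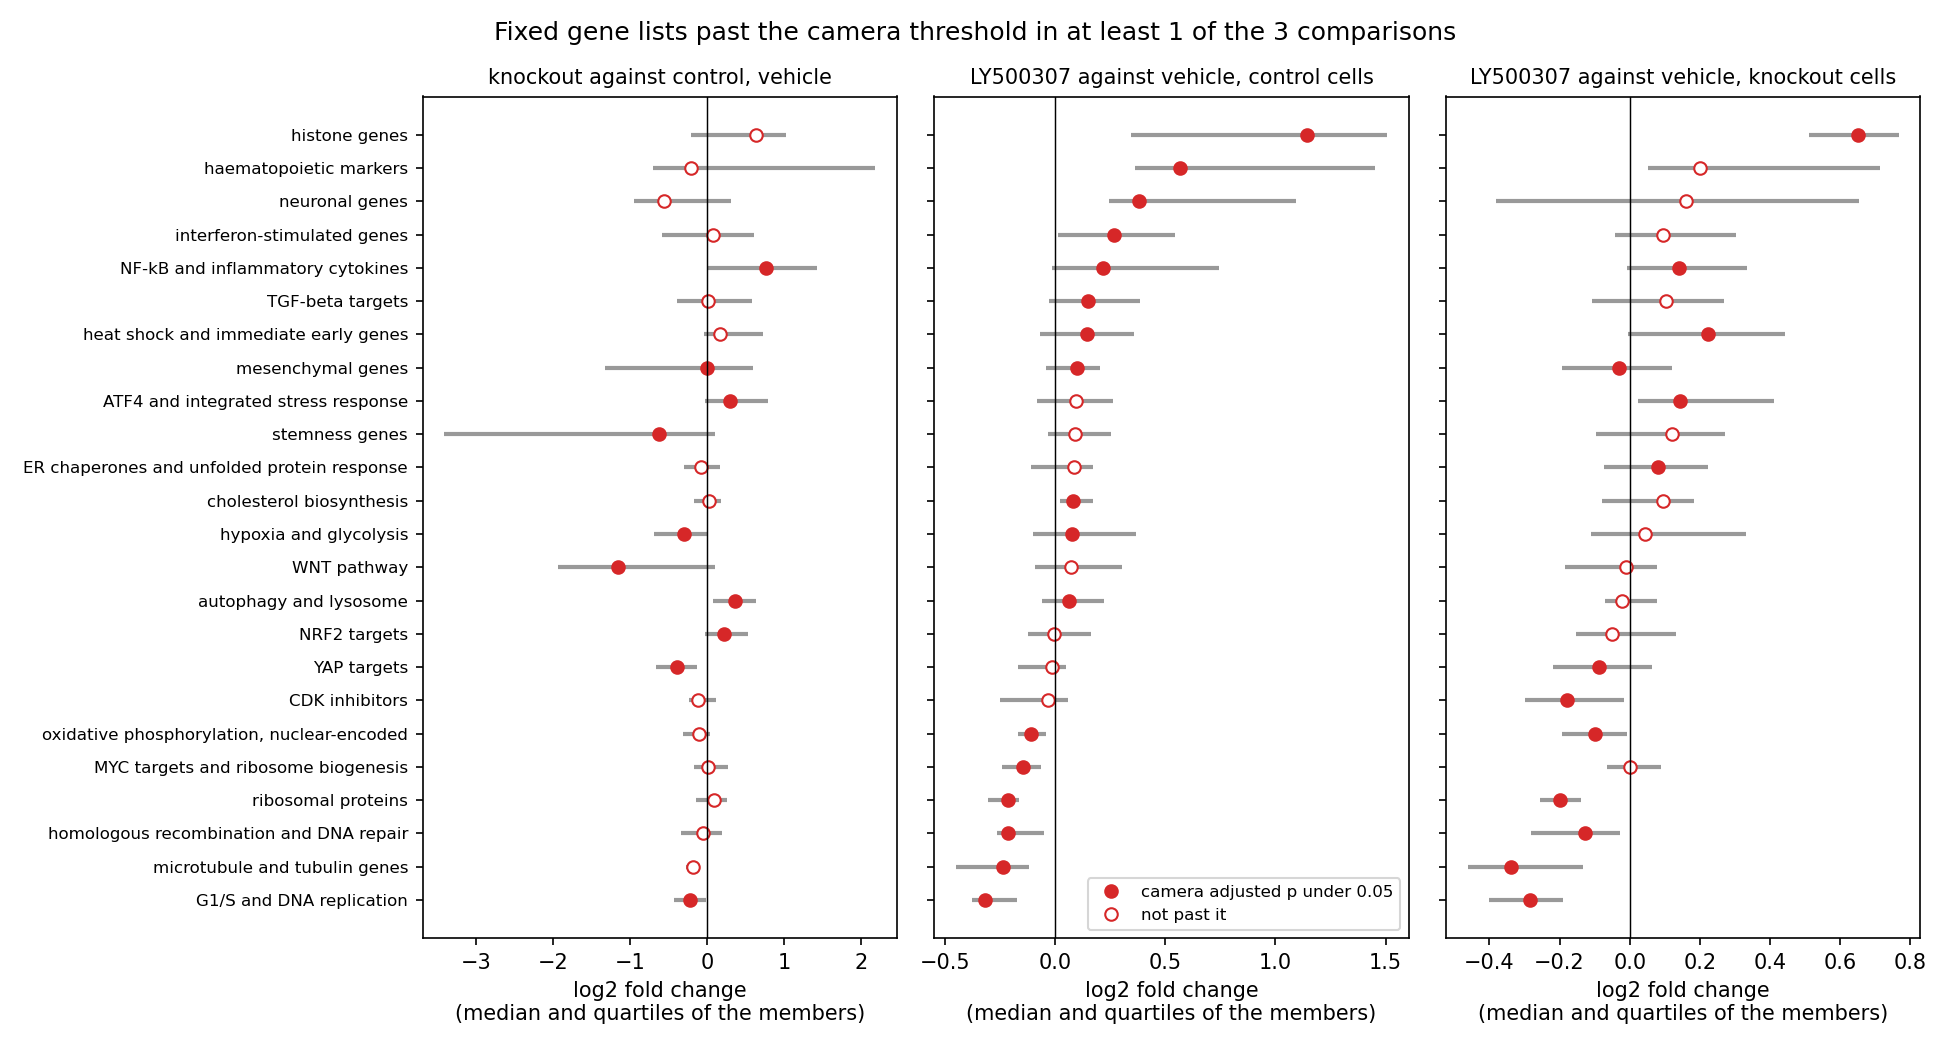
Median log2 fold change of the fixed gene lists that passed the camera threshold in any of the comparisons shown. These are knockout against control with vehicle, and LY500307 against vehicle in control and in knockout cells. Filled points passed the threshold in that comparison and open points did not. Lines give the middle 50% of members, and each panel has its own axis. G1/S and DNA replication genes lay at medians of -0.32 and -0.28 with LY500307 in control and knockout cells.

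The third comparison asked how LY500307 changed knockout cells. G1/S and DNA replication genes fell in 32 of 43 and microtubule and tubulin genes in 10 of 14, while heat shock and immediate early genes rose in 14 of 26. These lists passed with an estimated correlation (camera adjusted p = 0.00697, 0.0179 and 0.0257). FOSB, a subunit of the AP-1 transcription factor, rose from 12.2 ± 0.79 to 24.9 ± 1.26 CPM (1.02, SE 0.099). RAD54L, a recombination motor protein, changed by -0.86 (SE 0.078), and TUBA1B fell from 837 ± 35.1 to 501 ± 6.52 CPM. Other large rises were REEP6 (1.33, SE 0.18), DISP2 (1.18, SE 0.20), the secreted protein CRISPLD2 (1.08, SE 0.16), the glutamate transporter SLC1A3 (0.88, SE 0.086) and the hyaluronan synthase HAS3 (0.87, SE 0.14). Falls included the WNT antagonist DKK2 (-1.12, SE 0.15), RGS5 (-1.03, SE 0.18), LEPR (-0.99, SE 0.12) and the guidance ligand SLIT2 (-0.91, SE 0.12).

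In knockout cells the G1/S and DNA replication genes fell in 32 of 43 and rose in 0 (36 lower adjusted over the list alone; camera adjusted p = 4.93e-28, adjusted p = 0.00697 with an estimated correlation), with the helicase subunit MCM5 at -0.62, RRM2 at -0.48 and TYMS at -0.44. Microtubule and tubulin genes fell in 10 of 14 and rose in 0, the same adjusted over the list alone (camera adjusted p = 8.22e-18, adjusted p = 0.0179 with an estimated correlation), with TUBB at -0.63 and TUBB6 at -0.46. Heat shock and immediate early genes rose in 14 of 26 and fell in 1 (15 and 1 adjusted over the list alone; camera adjusted p = 9.34e-10, adjusted p = 0.0257 with an estimated correlation), with the transcription factor EGR1 at 0.54 and DUSP1 at 0.47; HSPA1B (0.73) shares reads with a near-identical copy. Ribosomal protein genes fell in 39 of 57 and rose in 1 (46 and 1 adjusted over the list alone; camera adjusted p = 8.22e-18, adjusted p = 0.236 with an estimated correlation). ATF4 and stress response genes rose in 14 of 33 and fell in 3 (19 and 3 adjusted over the list alone; camera adjusted p = 4.24e-06, adjusted p = 0.185 with an estimated correlation), with SLC3A2 at 0.41, the pseudokinase TRIB3 at 0.39 and the cysteine-producing enzyme CTH at 0.55. Homologous recombination genes fell in 15 of 34 and rose in 1 (16 and 2 adjusted over the list alone; camera adjusted p = 7.22e-06, adjusted p = 0.236 with an estimated correlation), with FANCI at -0.44 and BRIP1 at -0.43. Mesenchymal genes fell in 11 of 36 and rose in 5 (11 and 7 adjusted over the list alone; camera adjusted p = 0.00554, adjusted p = 0.236 with an estimated correlation, 0.348 on ranks); their median of -0.03 turned to 0.03 with library totals. COL6A3 changed by -0.75, COL1A1 by -0.68 and the matrix glycoprotein TNC by -0.56. NF-kB targets rose in 9 of 32 and fell in 2 (11 and 2 adjusted over the list alone; camera adjusted p = 0.00813, adjusted p = 0.257 with an estimated correlation), with IL1B at 0.61 and CXCL5 at -0.57. Histone genes rose in 4 of 7 and fell in 0 (6 higher adjusted over the list alone; camera adjusted p = 0.000173, adjusted p = 0.236 with an estimated correlation).

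Of the remaining lists that passed in knockout cells, each lost its call without at least 1 library. Oxidative phosphorylation genes fell in 11 of 42 and rose in 0 (12 lower adjusted over the list alone; camera adjusted p = 0.00813, adjusted p = 0.388 with an estimated correlation), with COX8A at -0.23 and ATP5B at -0.17, and camera adjusted p = 0.115 without knockout LY500307 replicate 2. Endoplasmic reticulum chaperones rose in 10 of 24 and fell in 2 (10 and 4 adjusted over the list alone; camera adjusted p = 0.0331, adjusted p = 0.236 with an estimated correlation), with HSPA5 at 0.35 and HERPUD1 at 0.44. Their camera adjusted p was 0.277 on ranks, 0.0699 without knockout vehicle replicate 2 and 0.101 without knockout LY500307 replicate 1. Inhibitors of cyclin-dependent kinases fell in 3 of 10 and rose in 1 (5 and 1 adjusted over the list alone; camera adjusted p = 0.0377, adjusted p = 0.236 with an estimated correlation), with CDKN2C at -0.64. For these the camera adjusted p was 0.0994 on ranks, 0.120 without knockout vehicle replicate 1 and 0.129 without knockout LY500307 replicate 2. YAP targets fell in 6 of 21 and rose in 2 (8 and 3 adjusted over the list alone; camera adjusted p = 0.0457, adjusted p = 0.236 with an estimated correlation), with CTGF at -0.41 and PTPN14 at -0.31. Their camera adjusted p was 0.115 without knockout vehicle replicate 1, 0.101 without knockout LY500307 replicate 1, 0.104 with library totals and 0.255 on ranks. Oestrogen-responsive genes rose in 6 of 17 and fell in 0 (6 and 1 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.0983). Haematopoietic (1 higher and 0 lower of 8, camera adjusted p = 0.334), endothelial (1 and 3 of 7, camera adjusted p = 0.501), and mesothelial and fibroblast markers (1 and 1 of 9, camera adjusted p = 0.817) did not pass, with the same numbers adjusted over the list alone. For endothelial markers the median of 0.23 and mean of 0.14 stood against a test towards lower values, and for mesothelial and fibroblast markers the median was 0.04 and the mean -0.15. Genes of G2/M and mitosis did not pass in knockout cells (6 higher and 11 lower of 41, 8 and 11 adjusted over the list alone, camera adjusted p = 0.464), with a median of 0.02, a mean of -0.02 and a test towards lower values.

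LY500307 changed 2759 genes in knockout cells, 1237 higher and 1522 lower, 84 and 21 of them by at least 2-fold. Scaling by library totals gave 2288 higher and 953 lower, and the count was 1422 without knockout vehicle replicate 2.

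The interaction asked whether the LY500307 effect differed between knockout and control cells, and the comparisons behind it share no library. TGFBI (chromosome 5, 135364677 to 135399507) rose from 83.8 ± 2.94 to 158 ± 3.52 CPM with LY500307 in control cells and stood at 126 ± 1.91 and 130 ± 0.98 CPM in knockout cells, an interaction of -0.87 (SE 0.073; edgeR quasi-likelihood test with Benjamini-Hochberg adjusted p = 1.55e-09). MMP2 rose by 1.00 on the log2 scale in control cells and went from 653 ± 0.721 to 765 ± 5.59 CPM in knockout cells (-0.77, SE 0.076). RPL22L1, a ribosomal protein paralog, fell from 172 to 111 CPM in control cells and rose from 65.4 ± 6.34 to 78.2 ± 2.32 CPM in knockout cells (0.89, SE 0.084), and is uncertain where it shares reads with related copies.

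Mesenchymal genes had a lower interaction in 10 of 36 and a higher one in 0 (12 and 1 adjusted over the list alone; camera adjusted p = 2.72e-12, adjusted p = 0.120 with an estimated correlation), with COL1A1 at -0.53 and FN1 at -0.37. MYC targets and ribosome biogenesis genes were higher in 3 of 36 and lower in 0 (18 higher adjusted over the list alone; camera adjusted p = 2.72e-12, adjusted p = 0.120 with an estimated correlation), with DDX21 at 0.28. Single genes with large interactions included SH2D1B (-1.42, SE 0.20), DKK2 (-1.42, SE 0.20) and the semaphorin SEMA6B (-1.295, SE 0.21). SH2D1B rose from 2.09 ± 0.481 to 5.78 ± 0.915 CPM in control cells and stood at 22.9 ± 0.212 and 23.6 ± 0.93 CPM in knockout cells. CHAC1 (1.47, SE 0.31) lost its call without knockout vehicle replicate 2 (1.33, edgeR adjusted p = 0.0972).

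Heat shock and immediate early genes were higher in 1 of 26 and lower in 0 (11 and 1 adjusted over the list alone; camera adjusted p = 0.00444, adjusted p = 0.216 with an estimated correlation). Interferon-stimulated genes were lower in 1 of 40, SAMD9 (-0.43, SE 0.075), and higher in 0 (4 lower adjusted over the list alone; camera adjusted p = 0.00444, adjusted p = 0.383 with an estimated correlation). That call was lost without control vehicle replicate 2 (camera adjusted p = 0.105) and without knockout LY500307 replicate 2 (0.0718). Autophagy and lysosome genes were lower in 1 of 31 and higher in 0 (6 lower adjusted over the list alone; camera adjusted p = 0.00613, adjusted p = 0.383 with an estimated correlation), and camera adjusted p was 0.0709 without control LY500307 replicate 2. ATF4 and stress response genes were higher in 3 of 33 and lower in 0 (4 higher adjusted over the list alone; camera adjusted p = 0.0134, adjusted p = 0.383 with an estimated correlation). Without knockout vehicle replicate 1, control LY500307 replicate 1 or knockout LY500307 replicate 2 the camera adjusted p of the ATF4 list was 0.0518, 0.1246 and 0.0534. TGF-beta targets were lower in 3 of 26 and higher in 0 (6 and 1 adjusted over the list alone; camera adjusted p = 0.0294, adjusted p = 0.353 with an estimated correlation, 0.435 on ranks). Without control vehicle replicate 1, knockout vehicle replicate 1, control LY500307 replicate 2 or knockout LY500307 replicate 1 it was 0.0731, 0.0786, 0.0709 and 0.0701. G1/S and DNA replication genes (0 higher and 1 lower of 43, camera adjusted p = 0.951) and microtubule and tubulin genes (0 and 1 of 14, camera adjusted p = 0.686) did not pass for the interaction, with the same numbers adjusted over the list alone.

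In the interaction 218 genes passed, 71 higher and 147 lower, 5 and 11 of them by at least 2-fold. The count was 118 and 134 without control vehicle replicates 1 and 2, 96 without knockout vehicle replicate 2, and 122 and 95 without control LY500307 replicates 1 and 2. Across the 13498 genes, LY500307 effects in control and knockout cells had a Pearson r of 0.389 and a Spearman rho of 0.534. The lists shared 575 genes that rose (153 for independent lists) and 898 that fell (213 for independent lists), while 21 and 7 genes went opposite ways.

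**Figure D4:**
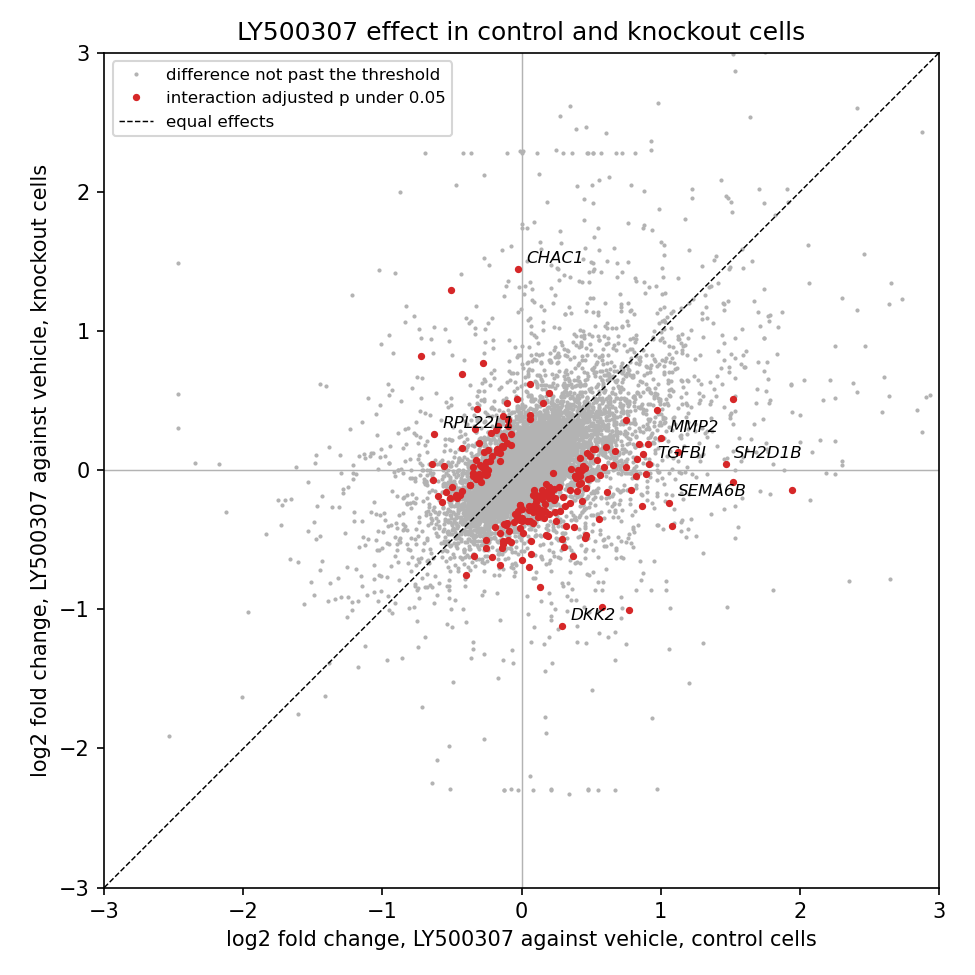
Log2 fold change of LY500307 against vehicle in control cells (x axis) and knockout cells (y axis) for each gene tested, within axes of -3 to 3 that hold 13449 genes and leave out 49; red points are genes with an interaction past the threshold and the dashed line marks equal effects. Across all 13498 genes Pearson's r was 0.389.

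The remaining comparisons set knockout against control under LY500307, and knockout cells with LY500307 against control cells with vehicle. Knockout effects under LY500307 followed those with vehicle across genes (Pearson r 0.931, libraries not shared), with 3578 genes higher and 3853 lower in both. BST2 rose by 7.43 (SE 0.27) and MGAM by 7.07 (SE 0.19), whose level in LY500307-treated control cells differed between libraries (0.785 ± 1.06 CPM). CDH19 was higher by a ratio of 471 (84.2 to 18650), and the neuronal gene FAM133A and EDA2R were at least 163-fold and 121-fold lower. YAP targets fell in 17 of 21 and rose in 2, the same adjusted over the list alone (camera adjusted p = 4.08e-10, adjusted p = 0.0747 with an estimated correlation), with ANKRD1 falling from 621 ± 53.4 to 3.01 ± 0.232 CPM. NF-kB targets rose in 23 of 32 and fell in 4 (23 and 5 adjusted over the list alone; camera adjusted p = 1.10e-07, adjusted p = 0.130 with an estimated correlation). Mesenchymal genes fell in 19 of 36 and rose in 13, the same adjusted over the list alone (camera adjusted p = 1.67e-06, adjusted p = 0.130 with an estimated correlation, 0.191 on ranks), with COL1A1 falling from 1100 ± 44.5 to 138 ± 15.0 CPM. Immediate early and heat shock genes rose in 19 of 26 and fell in 5, the same adjusted over the list alone (camera adjusted p = 0.00377, adjusted p = 0.130 with an estimated correlation), with EGR1 at 1.14 and FOS at 1.94. Of 13498 genes, 4401 were higher and 4533 lower in knockout cells under LY500307, 739 and 1162 of them by at least 2-fold, and arm medians again ran from -0.91 to 0.34. The balance of genes turned with library totals here too, to 4724 higher and 4221 lower.

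With both factors together, G1/S and DNA replication genes fell in 35 of 43 and rose in 2 (36 and 2 adjusted over the list alone; camera adjusted p = 1.01e-09, adjusted p = 0.0386 with an estimated correlation), with TYMS at -2.20 and E2F1 at -1.17. YAP targets fell in 14 of 21 and rose in 2, the same adjusted over the list alone (camera adjusted p = 3.93e-10, adjusted p = 0.0386 with an estimated correlation). NF-kB targets rose in 24 of 32 and fell in 3, the same adjusted over the list alone (camera adjusted p = 1.01e-09, adjusted p = 0.0879 with an estimated correlation). Microtubule and tubulin genes fell in 11 of 14 and rose in 0, the same adjusted over the list alone (camera adjusted p = 4.37e-05, adjusted p = 0.0879 with an estimated correlation). HMOX1 rose from 9.49 ± 0.99 to 143 ± 2.01 CPM and FOSB from 5.71 ± 0.124 to 24.9 ± 1.26 CPM, while CLEC5A was at least 921-fold higher and ODZ4, a teneurin adhesion protein, at least 108-fold lower. In this comparison 4467 genes were higher and 4702 lower, 986 and 1088 of them by at least 2-fold. With library totals the numbers were 5473 and 3823, as that scaling moved the median of all genes from -0.0061 to 0.0994.

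The knockout effect with vehicle and the LY500307 effect in control cells share the vehicle-treated control libraries. Across genes their Pearson r was 0.127 and Spearman rho 0.132. Simulated unchanged groups against the same controls gave an r of 0.548 (0.460 to 0.609). As these groups had no effects, their r cannot be compared with 0.127, since real effects widen the spread by which r is scaled. The covariance was 0.0628 against 0.0324 in the simulations, a difference of 0.0304. The simulated value leaves out genes without a count in vehicle-treated control cells, which the observed value includes. The difference therefore cannot be read as an excess over unchanged groups. The comparisons shared 738 genes that rose (511 for independent lists) and 893 that fell (627 for independent lists), and part of the excess may come from the shared controls. With 1 vehicle control library for each comparison, an alternative added after seeing the data, the r was 0.0730 and 0.0685. The covariance was 0.0534 and 0.0481. The shared genes were then 363 and 393 that rose (252 and 270 for independent lists) and 524 and 532 that fell (361 and 380). Without control vehicle replicates 1 and 2 the r was 0.249 and 0.279. Without control LY500307 replicates 1 and 2 it was 0.139 and 0.0720. Transcripts specific to knockout cells were seen mostly in control LY500307 replicate 2, where a trace of knockout material may account for them. Such a trace would raise these transcripts in both comparisons. The split of the vehicle controls does not remove it, and no setting dealt with both the trace and the shared controls. How much of the shared rises it accounts for was not tested.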

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

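Among the tests reported here, the comparison of replicates for transcripts specific to knockout cells was chosen only after the result was seen. The effect of LY500307 differed between knockout and control cells for 218 genes by the interaction term. Rises in the interaction were 1.47 for CHAC1, 1.12 for the matrix protease ADAMTS5, 0.89 for RPL22L1, 0.76 for ZNF48 and 0.69 for SNHG4 on the log2 scale. Falls were -1.48 for CADPS, -1.42 for SH2D1B, -1.42 for DKK2 and -1.295 for SEMA6B. The interaction of CLEC5A was -6.53, a fitted value that depends on the prior count, as vehicle-treated control cells had no count, and is no bound. Without control LY500307 replicate 2 it was -5.27 (edgeR adjusted p = 0.146). CHAC1 stood at 1.33 without knockout vehicle replicate 2 (edgeR adjusted p = 0.0972).

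ADAMTS5 lost its interaction call without control vehicle replicate 2, knockout vehicle replicate 2, control LY500307 replicate 2 or knockout LY500307 replicate 1 (edgeR adjusted p of 0.0511, 0.165, 0.0637 and 0.0991). SNHG4 lost it without control vehicle replicate 1 or control LY500307 replicate 2 (0.0625 and 0.0614 by edgeR). ZNF48 lost it without control vehicle replicates 1 and 2 (0.0708 and 0.0753), knockout vehicle replicates 1 and 2 (0.0593 and 0.156), control LY500307 replicate 2 (0.136) and knockout LY500307 replicate 2 (0.0740). CADPS lost it without control vehicle replicates 1 and 2 (0.244 and 0.0553), knockout vehicle replicates 1 and 2 (0.0521 and 0.0901), control LY500307 replicates 1 and 2 (0.154 and 0.0792) and knockout LY500307 replicate 1 (0.0621). By DESeq2 the adjusted p was 0.0982 for ZNF48 and 0.0608 for CADPS.

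Lists past the threshold in the interaction by camera lost their call with an estimated correlation (adjusted p of 0.120 to 0.383). Their median interactions were -0.1783 for mesenchymal genes, -0.1688 for interferon-stimulated genes, -0.04874 for TGF-beta targets and -0.05201 for autophagy and lysosome genes. The medians were 0.1521 for MYC targets and ribosome biogenesis, 0.0898 for ATF4 and the integrated stress response, and 0.06864 for heat shock and immediate early genes.

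Reads outside annotated genes, which no comparison used, made up a mean of 12.73% of uniquely aligned reads in vehicle-treated and 12.68% in LY500307-treated knockout cells. Alignments that were not unique averaged 52.77 per 100 uniquely aligned reads in vehicle-treated knockout cells. Both measures were higher than in control cells of the same treatment. Non-unique alignments were also fewer with LY500307 than with vehicle, at 46.57 against 50.07 in control cells and 49.71 against 52.77 in knockout cells.

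Transcripts specific to knockout cells, CLEC5A and MGAM among them, were seen at low level in LY500307-treated control cells, mostly in replicate 2. Of 26 genes at least 10-fold higher in vehicle-treated knockout than control cells and at 10 CPM or more, 22 (84.62%) were higher in replicate 2 than in replicate 1. A trace of knockout material in that library may account for this. Over all 26 genes a response to LY500307 was not excluded. The median excess over vehicle-treated control cells was 0.735% of the knockout level in replicate 1 (95% bootstrap interval over genes -0.00434 to 3.35). In replicate 2 it was 1.47% (0.898 to 5.40). For the 15 genes at least 20-fold and the 11 at least 50-fold higher it was 0.293% (-0.183 to 0.995) and -0.00434% (-0.416 to 0.32) in replicate 1, against 1.06% (0.161 to 2.46) and 0.928% (0.161 to 1.38) in replicate 2, which argues against a like response of these genes in both libraries.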

How the results depend on the processing

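The centring by chromosome arm and the removal of genes at least 10-fold higher in knockout were chosen only after the data were seen, as were the replicate block for correlations and the split of the vehicle controls. Of 3351 recomputed values of named genes, 3248 kept direction and side of the threshold, 90 lost the call, 4 gained it and 9 changed sign. Most of these genes were named for large changes or small p-values in the same data. These numbers therefore do not describe how stable calls are in general. Interaction calls of SLC7A5, ATF4, ODC1, NIP7, CTGF and ID3 were each lost without at least 1 library, and that of ID3 also by DESeq2 (adjusted p = 0.425). With a minimum 2-fold change 1873, 231, 105, 1901, 2074 and 16 genes passed for knockout with vehicle, LY500307 in control cells, LY500307 in knockout cells, knockout with LY500307, both factors and the interaction. These lie lower by construction. The interaction had 350 genes without a filter. Replicate number as a block gave 643 for the interaction and 8990, 4271, 3540, 9295 and 9503 for the others, more than without the block in each comparison. Deviations of same-numbered libraries had r of 0.000614 to 0.07 between groups. These r are small, but an r over all genes does not exclude a pairing of same-numbered libraries. DESeq2 gave 7843, 2630, 2143, 8087, 8397 and 187.

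With an estimated correlation 0, 2, 3, 0, 2 and 0 lists passed in that order, of 10, 17, 13, 13, 13 and 7. By fry, which compares a list with no other genes, 28 passed for knockout with vehicle, 36 for knockout with LY500307, 30 for both factors and 3 for the interaction. The correlation of LY500307 effects between cell populations was 0.519 with the stricter filter and 0.5693 over genes changed in either population, which leave fewer genes.

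Leaving out each library in turn gave 2160 to 2326 genes for LY500307 in control cells (2326 and 2160 without vehicle replicates 1 and 2, 2203 and 2188 without LY500307 replicates 1 and 2). The range was 1422 (without vehicle replicate 2) to 2257 in knockout cells. For the interaction it was 95 to 262, with 118 and 134 without control vehicle replicates 1 and 2, 96 without knockout vehicle replicate 2, and 122 and 95 without control LY500307 replicates 1 and 2. A lone library is assumed to vary like the other groups. The correlation of LY500307 effects ran from 0.270 to 0.332, and that of knockout and LY500307 effects from 0.0720 (without control LY500307 replicate 2) to 0.279 (without control vehicle replicate 2), with 0.249 without control vehicle replicate 1. Among these named genes, sign changes arose only in values that had not passed, each without 1 library. ESR1 ran from -0.75 to 0.34 for LY500307 in knockout cells and from -0.42 to 0.67 in the interaction, at counts too low to give a direction. Interaction values ran from -0.0804 to 0.0065 for HSP90AB1, from -0.0131 to 0.0728 for HSPA8 and from -0.12 to 0.018 for CTSD. The cause was not tested.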

Other observations

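The tests of arm-wide differences between populations, of fewer cycling cells and of tubulin calls kept with library totals were chosen only after the result was seen. In knockout against control cells under LY500307, MYC targets and ribosome biogenesis genes rose in 20 of 36 and fell in 6 (20 and 7 adjusted over the list alone; camera adjusted p = 0.0410, adjusted p = 0.348 with an estimated correlation). Their camera adjusted p was 0.0711 without knockout LY500307 replicate 1 and 0.138 with arm medians removed. Neuronal genes fell in 10 of 16 and rose in 2, the same adjusted over the list alone (camera adjusted p = 0.0484, adjusted p = 0.291 with an estimated correlation). Their camera adjusted p was 0.0572 without control LY500307 replicate 1 and 0.0736 and 0.0511 without knockout LY500307 replicates 1 and 2. With the replicate block it was 0.0617, and on ranks 0.0656. WNT pathway genes fell in 12 of 19 and rose in 2, the same adjusted over the list alone (camera adjusted p = 3.48e-06, adjusted p = 0.130 with an estimated correlation).

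With both factors together, ATF4 and stress response genes rose in 24 of 33 and fell in 6 (24 and 7 adjusted over the list alone; camera adjusted p = 9.70e-06, adjusted p = 0.139 with an estimated correlation), SLC3A2 by 1.60. Heat shock and immediate early genes rose in 18 of 26 and fell in 3, the same adjusted over the list alone (camera adjusted p = 0.000307, adjusted p = 0.0879 with an estimated correlation). Nuclear genes of oxidative phosphorylation fell in 23 of 42 and rose in 5, the same adjusted over the list alone (camera adjusted p = 0.0378, adjusted p = 0.550 with an estimated correlation). Their camera adjusted p was 0.0596 without control vehicle replicate 2, 0.0683 without knockout LY500307 replicate 2, 0.0952 with library totals and 0.0705 with arm medians removed.

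Knockout effects shifted whole chromosome arms. The SD of arm medians was 0.2767, against at most 0.0632 in 1000 shuffles of genes over arms, and arm medians with vehicle and with LY500307 had r = 0.995. After a smooth trend on GC content, length and expression was removed the SD was 0.2827, which argues against such a bias as the whole cause. The SD of LY500307 against vehicle was at most 8.378% of the 0.2767 for knockout, which met the criterion set beforehand against library size or normalization, but 1 factor per library moves all arms alike and cannot set them apart, so that the comparison decides nothing. A difference in copy number between the cell populations, from the knockout procedure or from clonal selection, may underlie the shifts, and the counts alone do not separate it from other regional differences.

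Of 10 alpha- and beta-tubulin genes, 6 were lower with LY500307 in control and 7 in knockout cells and 0 were higher. Their medians were -0.4394 (95% bootstrap interval over genes -0.527 to 0.0517) and -0.424 (-0.547 to -0.256). Fewer cycling or mitotic cells would lower G2/M and mitosis genes too, but their medians were -0.01845 (-0.098 to 0.0286) and 0.01932 (-0.037 to 0.0639), while G1/S and DNA replication genes fell (-0.32 and -0.28), so that a shift between phases stays open. With library totals the medians were -0.3667 (-0.454 to 0.124) and -0.3648 (-0.488 to -0.196). The criterion set beforehand, an interval below 0 in both populations, was thus not met in control cells. By the criterion added afterwards, the 6 and 7 genes called lower stayed lower. Library totals moved the median of all genes only from 0.0052 to 0.0779 in control and from 0.0103 to 0.0697 in knockout cells. So small a shift could hardly undo these calls. The outcome shows only that they did not rest on this choice of scaling. The mean of the 10 genes differed from that of 14 other tubulin-related genes by a 2-sided permutation test over genes (p = 0.0432 in control and 0.00407 in knockout cells). The test treats related genes as independent, and its p-values do not measure the spread between libraries. Of the 14, 3 and 6 were lower too and 1 higher in each population, with medians of -0.109 and -0.0731. A larger change of alpha- and beta-tubulin messages, which fall when free tubulin rises, may be at work, although paralogs share reads and tubulin protein was not measured here.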
